A study of Caenorhabditis elegans with 20 samples.

How the data were processed

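Poly(A) RNA of whole young adult animals was measured by stranded mRNA sequencing in 20 libraries, which make up 12 replicates in 4 groups of 3: WT and ns889, each without and with the mold. Per the labels, animals were grown on NGM plates with Escherichia coli OP50, for 48 hours from L1 arrest at 20 C. The authors deposited a table of counts per gene, without normalization. Per the submitters' processing notes, FastQC 0.11.12, STAR 2.4a and featureCounts were used with the WBcel235 genome, and edgeR 3.28.1 and limma 3.42.2 are named as well. The version of featureCounts, the strand setting and the annotation release are not given in the sources used here. Replicate 1 of each group has 1 sequencing run and replicates 2 and 3 have 2 runs each, which were summed. The 8 pairs of runs differed by a chi-square of 1.08 to 1.12 per degree of freedom, and replicates of a group by 12.1 to 193.

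Replicates held 95998037 to 115940062 counts. Of 46904 gene IDs, 46817 were found in annotation release 115, and 32349 had the same start and end there. Mitochondrial DNA gave 1.36 to 1.63% of counts. Genes were filtered with filterByExpr, scaled by TMM and tested with edgeR's quasi-likelihood test (estimateDisp, robust glmQLFit, glmQLFTest; R 4.3.3, edgeR 4.0.16) in 1 model of group means over all 12 replicates, without covariates. The contrasts were mold against no mold in each genotype, ns889 against WT in each condition, and the difference of both mold responses. p-values were adjusted by Benjamini-Hochberg over the genes tested, with a threshold of 0.05. Errors beside log2 fold changes are standard errors.

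The tests, the gene lists and the rule for named genes were fixed before the data were examined. There were 49 lists of detoxification, immune, stress, metabolic and developmental genes and of tissue markers; 48 were tested. The list of respiratory chain genes encoded in mitochondrial DNA was not tested, since its symbols did not match those in the table. Lists with at least 5 tested members were tested with camera (limma 3.58.1) at a preset inter-gene correlation of 0.01, adjusted over the lists of a comparison, and again with a correlation estimated from the data. With the estimated correlation only the dod list passed, in the response of ns889 and in the difference of the responses. For each comparison of groups the named genes were the 10 highest and 10 lowest log2 fold changes past the threshold, with a mean of at least 5 CPM and no overlap between the replicates (no overlap criterion for the difference). They also included up to 4 members with the smallest p of each list, or up to 2 of the most abundant where none passed, and always nhr-45, nhr-156, hsp-6, hsp-60, hsp-4 and gst-4; some are left out for length.

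The alternatives were RLE size factors, DESeq2 1.42.0, limma-voom, no filter, a filter of 5 CPM, the first run only, the replicate number as a block, a fit of only the 2 groups compared, a minimum absolute log2 fold change of 1, and leaving out replicates. Leaving out WT without mold replicate 1 and WT with mold replicate 3 together was chosen after seeing the data. The tests were tried on simulated changes in 50 genes per fold: 2 to 48% of genes changed 1.5-fold, 40 to 74% of those changed 2-fold and 90 to 100% of those changed 4-fold were found. At 8-fold 88 to 98% were found. The lowest shares at 1.5-fold (2%) and 2-fold (40%) were those of the difference of the responses. Each gene was drawn independently from the trended dispersion, without libraries that stood apart, so the real shares may be lower. Figures were drawn with matplotlib 3.10.9. Bias from GC content was not tested, since no genome sequence was at hand.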

Results

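Poly(A) RNA from whole young adult Caenorhabditis elegans was sequenced in 4 groups of 3 replicates. Wild-type (WT) and ns889 animals were each grown on plates without mold or with the mold Penicillium brevicompactum. ns889 is an allele, and the labels do not name the gene it affects. The 12 replicates held 95998037 to 115940062 counted reads each, so that 3 counts, taken as the floor of detection, equal 0.0259 to 0.0313 CPM (counts scaled to the library total, and by TMM for the values of genes). This floor covers counting error only. The labels do not say that the replicates were separate cultures, so the p-values measure the spread between these samples. Of 46904 genes in the deposited table, 16980 were abundant enough to test. The first principal component held 34.7% of the variance and the second 22.7%. WT without mold replicate 1 lay farthest from the other replicates of its group (root mean square log2 difference 0.445), followed by WT with mold replicate 3 (0.372) and replicate 1 (0.334). The other 9 libraries lay between 0.113 and 0.252.

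The first comparison asked which genes changed when WT animals met the mold. Genes of detoxifying enzymes were among those that rose. cyp-13A8, a cytochrome P450 gene (WBGene00011674, chromosome II, 9805627 to 9807532 in WBcel235), went from 0.208 ± 0.0657 to 96.9 ± 13.3 CPM (mean ± SD, n = 3), a log2 fold change of 8.85 ± 0.51 (SE). Its adjusted p was 2.79e-06. gst-33, a glutathione S-transferase gene (WBGene00001781, chromosome V, 3467453 to 3468545), went from 0.351 ± 0.186 to 91.4 ± 33.2 CPM (log2 fold change 8.05 ± 0.53). Further rises were seen in cyp-33C2 (6.33 ± 0.65), cyp-13A12 (6.05 ± 0.43), gst-44 (5.95 ± 0.38), cyp-14A4 (5.31 ± 0.27) and stdh-2, a steroid dehydrogenase family gene (5.48 ± 0.45). The gene lact-6, which encodes a protein with a beta-lactamase domain (WBGene00007358, chromosome IV, 17429637 to 17431968), fell from 13.6 ± 4.42 CPM to 0.0451 ± 0.0167 CPM. Its log2 fold change was -8.18 ± 0.46 (adjusted p = 2.27e-06).

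**Figure D1:**
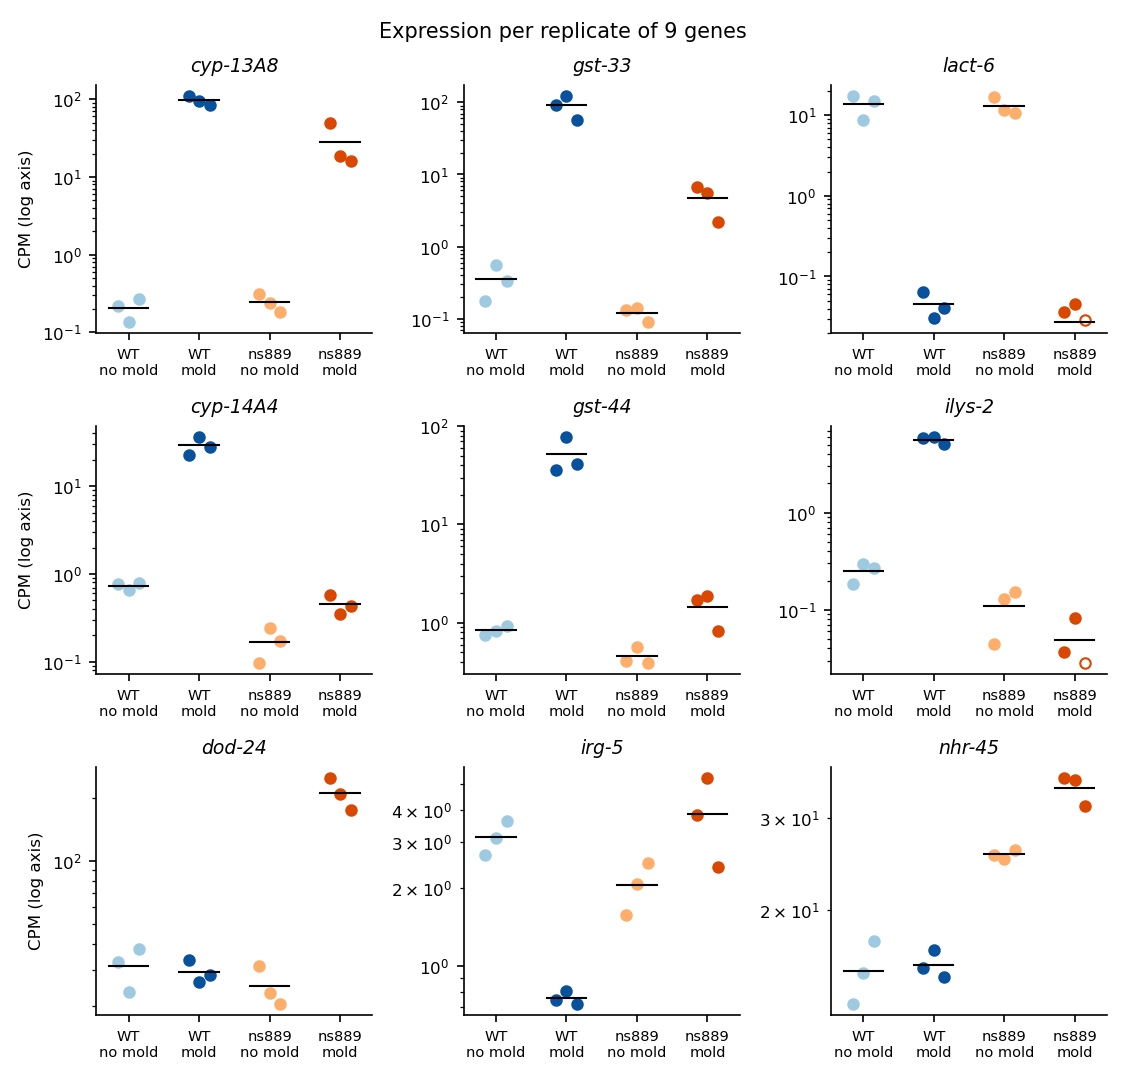
Expression of 9 genes in CPM on log axes, 1 point per replicate and a black line at the mean of 3 replicates; open points lie under the floor of 3 counts and are drawn at that floor. cyp-13A8, gst-33 and lact-6 moved with mold in both genotypes, and dod-24 reached 212 CPM with mold in ns889 against 29.4 CPM in WT.

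More cytochrome P450 genes rose than fell in WT: 19 of 69 measured members rose and 7 fell (24 higher and 9 lower adjusted over the list alone). Camera on cytochrome P450 genes gave adjusted p = 8.87e-08 (adjusted p = 0.127 with an estimated correlation). UDP-glycosyltransferase genes, whose products attach sugars to foreign compounds, split in direction: 7 of 64 rose and 9 fell (9 higher and 14 lower adjusted over the list alone), among the latter ugt-15 (-6.29 ± 0.34), ugt-66 (-2.51 ± 0.24), ugt-63 (-2.50 ± 0.24) and ugt-8 (-2.46 ± 0.23). Of 48 glutathione S-transferase genes, 3 rose and 3 fell (7 higher and 4 lower adjusted over the list alone). Among 200 nuclear hormone receptor genes 4 rose and 3 fell (3 higher and 2 lower adjusted over the list alone): nhr-8, which is needed for resistance to foreign compounds, rose (1.33 ± 0.17), and nhr-114 (-1.15 ± 0.19) fell. nhr-45 (0.041 ± 0.11, adjusted p = 0.829) and nhr-156 (0.013 ± 0.20, adjusted p = 0.974) did not pass. Leaving out single libraries moved these counts by over 1.5 times. Cytochrome P450 genes numbered 10 higher and 2 lower without WT without mold replicate 2, 9 and 2 without WT without mold replicate 3, 10 and 4 without WT with mold replicate 2, and 12 and 2 without WT with mold replicate 3. UDP-glycosyltransferase genes numbered 8 higher and 16 lower without WT without mold replicate 1. Glutathione S-transferase genes numbered 5 higher and 6 lower without WT without mold replicate 1, and 3 and 1 without WT without mold replicate 2 or WT with mold replicate 2. Nuclear hormone receptor genes numbered 12 higher and 14 lower without WT without mold replicate 1, 3 and 1 without WT without mold replicate 3, and 2 and 2 without WT with mold replicate 2 or 3.

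Immune and metabolic genes moved as well. Of 13 lysozyme genes 3 rose, ilys-2 (4.51 ± 0.34) and lys-2 (2.11 ± 0.26) among them, and 1 fell (6 higher and 2 lower adjusted over the list alone). The list's mean (0.41) and its test pointed up, its median (-0.16) down. Camera on lysozyme genes gave adjusted p = 0.00960 (adjusted p = 0.646 with an estimated correlation). The infection response genes irg-4 (-2.46 ± 0.27) and irg-5 (-2.05 ± 0.28) fell (0 higher and 2 lower of 8, and 1 higher and 3 lower adjusted over the list alone). Genes of fatty acid synthesis and desaturation fell: 6 of 20 were lower and 0 higher (1 higher and 10 lower adjusted over the list alone), including the desaturase genes fat-5 (-2.70 ± 0.33) and fat-3 (-0.94 ± 0.079). Camera on fatty acid synthesis and desaturation genes gave adjusted p = 1.06e-05 (adjusted p = 0.127 with an estimated correlation). Of 49 lipid breakdown genes 7 rose and 4 fell (16 higher and 8 lower adjusted over the list alone), and the lipase genes lipl-3 (3.41 ± 0.35) and lipl-5 (1.81 ± 0.20) were among those that rose. Cathepsin-type protease genes rose, 5 of 24 with 0 lower (11 higher and 1 lower adjusted over the list alone), among them cpr-3 (1.66 ± 0.18) and cpr-1 (1.32 ± 0.21). Camera on cathepsin-type protease genes gave adjusted p = 0.00082 (adjusted p = 0.583 with an estimated correlation). Of 133 C-type lectin genes 9 rose and 12 fell (16 higher and 19 lower adjusted over the list alone). Epidermal antimicrobial peptide genes rose in 4 of 16 cases with 0 lower (6 higher and 0 lower adjusted over the list alone). Camera on epidermal antimicrobial peptide genes gave adjusted p = 0.00426 (adjusted p = 0.713 with an estimated correlation). C-type lectin genes numbered 16 higher and 27 lower without WT without mold replicate 1, 4 and 4 without WT without mold replicate 2, 3 and 3 without WT without mold replicate 3, 9 and 20 without WT with mold replicate 1, 3 and 2 without WT with mold replicate 2, and 9 and 4 without WT with mold replicate 3. Epidermal antimicrobial peptide genes numbered 4 higher and 1 lower without WT without mold replicate 1, 0 and 0 without WT without mold replicate 2 or WT with mold replicate 2, 1 and 0 without WT without mold replicate 3, and 3 and 1 without WT with mold replicate 1. The epidermal antimicrobial peptide list no longer passed camera without WT without mold replicate 1 (adjusted p = 0.199) and WT with mold replicate 1 (adjusted p = 0.101, range with 1 library left out 5.87e-07 to 0.199). Lysozyme genes numbered 3 higher and 2 lower without WT without mold replicate 1 or WT with mold replicate 1, and 3 and 0 without WT without mold replicate 2 or 3 or WT with mold replicate 2 or 3. The lysozyme list no longer passed camera without WT without mold replicate 1 (adjusted p = 0.125, range with 1 library left out 0.000455 to 0.125). Fatty acid synthesis and desaturation genes numbered 1 higher and 10 lower without WT without mold replicate 1, 0 and 2 without WT without mold replicate 2 or 3 or WT with mold replicate 2 or 3, and 1 and 7 without WT with mold replicate 1. Lipid breakdown genes numbered 13 higher and 8 lower without WT without mold replicate 1, 3 and 3 without WT without mold replicate 2, 4 and 2 without WT without mold replicate 3, and 5 and 2 without WT with mold replicate 3. Cathepsin-type protease genes numbered 6 higher and 2 lower without WT without mold replicate 1, 3 and 0 without WT without mold replicate 2 or 3, and 2 and 0 without WT with mold replicate 2. The cathepsin-type protease list no longer passed camera without WT without mold replicate 1 (adjusted p = 0.0585, range with 1 library left out 2.51e-06 to 0.0585).

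Sperm genes were lower with mold in WT: 12 of 52 fell and 0 rose (0 higher and 30 lower adjusted over the list alone), with a median log2 fold change of -0.62, for example spe-42 (-1.28 ± 0.23) and spe-43 (-1.65 ± 0.34). Camera on sperm genes gave adjusted p = 7.81e-14 (adjusted p = 0.646 with an estimated correlation). Of 29 major sperm protein genes 1 fell (0 higher and 17 lower adjusted over the list alone, median -0.55). Camera on major sperm protein genes gave adjusted p = 3.63e-14 to 1.29e-05 with 1 library left out, and the list did not pass with an estimated correlation. Of 21 oocyte and eggshell genes 0 passed (median 0.30; edgeR's quasi-likelihood test). Camera on oocyte and eggshell genes gave adjusted p = 4.51e-05 (adjusted p = 0.794 with an estimated correlation). The mean log2 deviation of the sperm list in WT was -0.13, 0.38 and 0.41 in replicates 1 to 3 without mold and -0.14, -0.38 and -0.94 with mold. The groups did not overlap, but replicates 1 of both lay next to each other. Sperm genes numbered 1 higher and 32 lower without WT without mold replicate 1, 0 and 0 without WT without mold replicate 2 or 3 or WT with mold replicate 2, 0 and 35 without WT with mold replicate 1, and 0 and 1 without WT with mold replicate 3. Major sperm protein genes numbered 0 higher and 13 lower without WT without mold replicate 1, 0 and 0 without WT without mold replicate 2 or 3 or WT with mold replicate 2 or 3, and 0 and 21 without WT with mold replicate 1. Oocyte and eggshell genes numbered 18 higher and 0 lower without WT without mold replicate 1, and 1 and 0 without WT with mold replicate 1.

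edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment placed 283 genes higher and 781 lower with mold in WT. Of these 1064 genes, 939 had no overlap between the groups' replicates, as did 2979 of the 16980 tested genes, where chance gives 10%. Single libraries moved these counts: 2263 genes were higher and 2547 lower without WT without mold replicate 1, 106 and 75 without its replicate 2, 97 and 62 without its replicate 3. They were 448 and 1564 without WT with mold replicate 1, 115 and 98 without its replicate 2, and 162 and 103 without its replicate 3. Leaving out WT without mold replicate 1 and WT with mold replicate 3 together, chosen after seeing the data, gave 1642 and 2218. Among the genes named for WT, spe-42 was lost without WT without mold replicates 2 (adjusted p = 0.0530) and 3 (0.0579) and WT with mold replicate 2 (0.0588, range over its alternatives 1.37e-06 to 0.155). spe-43 was lost without WT without mold replicates 2 (adjusted p = 0.0653) and 3 (0.107) and WT with mold replicates 2 (0.0819) and 3 (0.0888, range 5.12e-05 to 0.219).

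The second comparison asked which genes changed when ns889 animals met the mold. Again cytochrome P450 and glutathione S-transferase genes were among those that rose. cyp-13A12 rose from 0.0319 ± 0.00310 CPM, about the floor, to 20.8 ± 10.2 CPM (mean ± SD, n = 3), a fitted log2 fold change of 9.29 ± 0.63 (SE). Its adjusted p was 1.62e-05. cyp-13A8 rose to 27.8 ± 18.2 CPM (6.81 ± 0.47) and gst-33 to 4.74 ± 2.30 CPM (5.27 ± 0.55). dod-24, a gene named as downstream of the transcription factor DAF-16 (WBGene00007875, chromosome IV, 12940106 to 12941405), rose from 25.1 ± 5.63 to 212 ± 38.2 CPM (3.08 ± 0.21, adjusted p = 1.59e-05). Its neighbour C32H11.4 also rose (3.04 ± 0.35). lact-6 fell to about the floor as in WT (0.0275 ± 0.0243 CPM, fitted log2 fold change -8.82 ± 0.49). Others that fell were T16G1.7 (-3.09 ± 0.26), ugt-66 (-2.69 ± 0.24), ugt-63 (-2.62 ± 0.24), ugt-8 (-2.50 ± 0.23) and the lysozyme gene lys-7 (-2.22 ± 0.25).

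In ns889, 10 of 69 cytochrome P450 genes rose and 6 fell (10 higher and 8 lower adjusted over the list alone), the latter including cyp-35D1 (-2.49 ± 0.30). Camera on cytochrome P450 genes gave adjusted p = 0.0274 (adjusted p = 0.408 with an estimated correlation). More UDP-glycosyltransferase genes fell than rose, 13 of 64 against 3 higher (11 higher and 19 lower adjusted over the list alone), for example ugt-15 (-4.70 ± 0.29) and ugt-41 (-1.92 ± 0.13). Camera on UDP-glycosyltransferase genes gave adjusted p = 4.78e-06 (adjusted p = 0.192 with an estimated correlation). Glutathione S-transferase genes rose in 7 of 48 cases and fell in 1 (8 higher and 6 lower adjusted over the list alone), and gst-38 (4.14 ± 0.51) was among those that rose. Of 9 dod genes 4 rose and 1 fell (6 higher and 2 lower adjusted over the list alone), a list that passed under both correlations. Camera on dod genes gave adjusted p = 1.37e-08 (adjusted p = 0.00892 with an estimated correlation). dod-19 (1.44 ± 0.23) and dod-17 (1.51 ± 0.25) rose with dod-24. Of 180 F-box genes 20 rose and 1 fell (26 higher and 1 lower adjusted over the list alone). Camera on F-box genes gave adjusted p = 2.8e-07 (adjusted p = 0.109 with an estimated correlation). Cytochrome P450 genes numbered 3 higher and 4 lower without ns889 without mold replicate 1, 5 and 2 without ns889 without mold replicate 2, 6 and 4 without ns889 without mold replicate 3, 6 and 2 without ns889 with mold replicate 1, and 4 and 4 without ns889 with mold replicate 2. The cytochrome P450 list no longer passed camera without ns889 without mold replicate 1 (adjusted p = 0.301, range with 1 library left out 0.000414 to 0.301). Glutathione S-transferase genes numbered 5 higher and 2 lower without ns889 without mold replicate 1, 5 and 0 without ns889 without mold replicate 2 or ns889 with mold replicate 1, and 7 and 0 without ns889 with mold replicate 3. dod genes numbered 4 higher and 0 lower without ns889 without mold replicate 1 or ns889 with mold replicate 2, and 3 and 0 without ns889 without mold replicate 2 or 3 or ns889 with mold replicate 1 or 3. F-box genes numbered 8 higher and 0 lower without ns889 without mold replicate 1 or ns889 with mold replicate 1 or 2, 7 and 0 without ns889 without mold replicate 2, and 13 and 0 without ns889 without mold replicate 3.

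Among 133 C-type lectin genes, whose products bind sugars, 16 rose and 6 fell in ns889 (20 higher and 12 lower adjusted over the list alone), with clec-17 (5.39 ± 0.45), clec-67 (3.33 ± 0.45) and clec-66 (2.48 ± 0.30) among the risers. The lysozyme list held 2 risers, lys-2 (2.42 ± 0.27) among them, and 3 that fell, with ilys-5 (-1.87 ± 0.18) among them (3 higher and 7 lower adjusted over the list alone). Camera on lysozyme genes gave adjusted p = 0.00179 (adjusted p = 0.285 with an estimated correlation). Epidermal antimicrobial peptide genes rose in 4 of 16 cases with 0 lower, as many as in WT (7 higher and 0 lower adjusted over the list alone), among them cnc-4 (1.70 ± 0.22) and nlp-30 (2.26 ± 0.35). Camera on epidermal antimicrobial peptide genes gave adjusted p = 4.79e-08 (adjusted p = 0.192 with an estimated correlation). Fatty acid genes fell in 4 of 20 cases with 0 higher (0 higher and 4 lower adjusted over the list alone). Camera on fatty acid synthesis and desaturation genes gave adjusted p = 3.27e-07 (adjusted p = 0.0750 with an estimated correlation). Methionine and one-carbon cycle genes fell in 5 of 15 cases (0 higher and 7 lower adjusted over the list alone), including ahcy-1 (-0.49 ± 0.066). Camera on methionine and one-carbon cycle genes gave adjusted p = 2.8e-07 (adjusted p = 0.192 with an estimated correlation). Yolk protein (vitellogenin) genes fell in 3 of 6 cases (0 higher and 6 lower adjusted over the list alone). Camera on vitellogenin genes gave adjusted p = 1.37e-08 (adjusted p = 0.192 with an estimated correlation). Cathepsin-type protease genes rose in 5 of 24 (9 higher and 5 lower adjusted over the list alone), among them asp-14 (2.07 ± 0.20) and cpr-3 (1.66 ± 0.18). Camera on cathepsin-type protease genes gave adjusted p = 0.0109 (adjusted p = 0.368 with an estimated correlation). C-type lectin genes numbered 10 higher and 6 lower without ns889 without mold replicate 1, 8 and 4 without ns889 without mold replicate 2, and 10 and 4 without ns889 with mold replicate 1. Lysozyme genes numbered 1 higher and 3 lower without ns889 without mold replicate 1, 1 and 2 without ns889 without mold replicate 2, and 2 and 5 without ns889 with mold replicate 3. Epidermal antimicrobial peptide genes numbered 2 higher and 0 lower without ns889 without mold replicate 2 or 3 or ns889 with mold replicate 1. Fatty acid synthesis and desaturation genes numbered 0 higher and 1 lower without ns889 without mold replicate 1 or 2 or ns889 with mold replicate 1 or 2, and 0 and 2 without ns889 with mold replicate 3. Methionine and one-carbon cycle genes numbered 0 higher and 1 lower without ns889 without mold replicate 1 or 2 or ns889 with mold replicate 2, and 0 and 2 without ns889 without mold replicate 3 or ns889 with mold replicate 1. Vitellogenin genes numbered 0 higher and 1 lower without ns889 without mold replicate 1, and 0 and 0 without ns889 without mold replicate 2 or 3 or ns889 with mold replicate 1 or 2. Cathepsin-type protease genes numbered 3 higher and 1 lower without ns889 without mold replicate 1, and 3 and 0 without ns889 without mold replicate 2 or 3 or ns889 with mold replicate 1 or 2. The cathepsin-type protease list no longer passed camera without ns889 without mold replicate 1 (adjusted p = 0.0690, range with 1 library left out 0.00154 to 0.0690).

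The sperm list was lower and the moulting and cuticle list higher with mold in ns889 by camera. Of 52 sperm genes 0 rose and 0 fell with mold by edgeR's quasi-likelihood test (0 higher and 0 lower adjusted over the list alone), with a median log2 fold change of -0.29. Camera on sperm genes gave adjusted p = 0.00041 (adjusted p = 0.735 with an estimated correlation). The mean log2 deviation of the sperm list in ns889 was 0.36, 0.24 and 0.25 in replicates 1 to 3 without mold and -0.11, 0.084 and -0.027 with mold. Of 30 moulting and cuticle genes 1 rose and 0 fell (3 higher and 0 lower adjusted over the list alone; median 0.83). Camera on moulting and cuticle genes gave adjusted p = 1.8e-05 (adjusted p = 0.408 with an estimated correlation). Their mean log2 deviation was -0.31, -0.072 and 0.32 without mold and 1.08, 0.49 and 0.58 with mold. Moulting and cuticle genes numbered 0 higher and 0 lower without ns889 without mold replicate 1 or 2 or ns889 with mold replicate 1 or 2.

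edgeR's test with Benjamini-Hochberg adjustment placed 316 genes higher and 218 lower with mold in ns889, and all 534 had no overlap between the replicates, as did 5373 of the tested genes against 10% by chance. Counts fell when single libraries were left out: 158 higher and 105 lower without ns889 without mold replicate 1, 128 and 81 without its replicate 2, 208 and 116 without its replicate 3. They were 174 and 80 without ns889 with mold replicate 1, and 173 and 81 without its replicate 2. Without WT without mold replicate 1 and WT with mold replicate 3, chosen after seeing the data, they were 809 and 1215. nhr-45 (0.43 ± 0.10, adjusted p = 0.0488) and the oxidative stress gene gst-4 (0.82 ± 0.20, adjusted p = 0.0441) passed narrowly. nhr-45 was lost without any 1 of the 6 libraries (adjusted p 0.0638 to 0.198). gst-4 was lost without ns889 without mold replicates 1 (adjusted p = 0.187), 2 (0.161) and 3 (0.0849) and ns889 with mold replicates 1 (0.200) and 2 (0.0737, range over its alternatives 0.00100 to 0.200). gst-33 was lost without replicate 1 of every group (adjusted p = 0.0686, range 1e-18 to 0.0686).

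Both genotypes shared a part of their response. Of 283 genes higher in WT and 316 in ns889, 127 were shared, against 5.27 expected for independent calls. Of 781 and 218 lower genes 102 were shared, against 10.03 expected. 5 genes were called in opposite directions. Shared risers included cyp-13A8, cyp-13A12, gst-33, stdh-2, nhr-8 (1.33 ± 0.17 in WT and 1.26 ± 0.16 in ns889), lys-2 (2.11 ± 0.26 and 2.42 ± 0.27) and cpr-3 (1.66 ± 0.18 and 1.66 ± 0.18). Shared among the lower genes were lact-6, ugt-66, ugt-63, ugt-8, ugt-15 and fat-3 (-0.94 ± 0.079 and -0.93 ± 0.079). Log2 fold changes of both responses correlated across genes, which are not independent replicates (Pearson r = 0.547 over all tested genes and 0.711 over those with a mean of at least 5 CPM). Of the genes higher in WT 266 of 283 had a positive change in ns889, and of those lower 770 of 781 a negative one. The shared counts without a single library ran from 52 to 197 higher and 46 to 220 lower, moving by over 1.5 times without WT without mold replicates 1 (197 and 220), 2 (62 and 52) and 3 (56 and 46), WT with mold replicate 2 (61 and 55), ns889 without mold replicates 1 (60 and 60), 2 (52 and 51) and 3 (71 and 60) and ns889 with mold replicates 1 (78 and 59), 2 (82 and 66) and 3 (82 higher). Without WT without mold replicate 1 and WT with mold replicate 3, chosen after seeing the data, they were 323 and 884. stdh-2 was lost in ns889 with limma-voom (adjusted p = 0.0597, range over its alternatives 1.08e-07 to 0.0597).

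**Figure D2:**
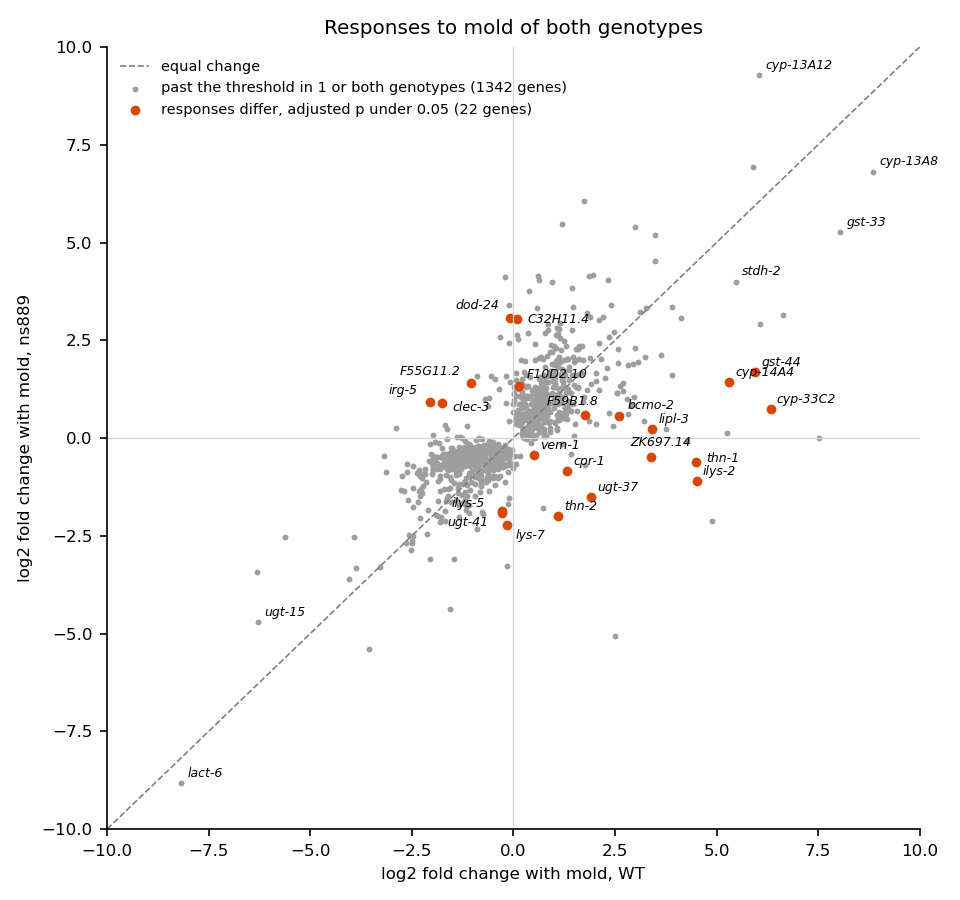
Log2 fold change with mold in ns889 against that in WT, 1 point per gene: grey for 1342 genes past the threshold in at least 1 genotype whose difference did not pass, orange for the 22 genes whose difference passed. Of the genes higher in WT 266 of 283 lie above 0 in ns889, and of those lower 770 of 781 lie below 0.

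The third comparison asked how ns889 animals differed from WT without mold. F11C3.1, a protein-coding gene (WBGene00008695, chromosome I, 14867924 to 14871467 in WBcel235), was 221-fold higher in ns889, at 181 ± 26.3 CPM against 0.819 ± 0.102 CPM (mean ± SD, n = 3). Its log2 fold change was 7.79 ± 0.21 (SE, adjusted p = 8.64e-10). C08F11.7 (3.88 ± 0.22), H17B01.2 (3.19 ± 0.18) and its neighbour Y51H7C.1 (1.90 ± 0.13), M04C9.4 (2.27 ± 0.24) and jmjc-1, a JmjC-domain gene (2.06 ± 0.12), were also higher. So were fkb-5, a peptidyl-prolyl isomerase gene (1.75 ± 0.14), the thioredoxin-domain gene txdc-12.1 (1.76 ± 0.17) and phy-2, a collagen prolyl 4-hydroxylase gene (0.82 ± 0.091). Lower in ns889 were cyp-13A12, at 0.0319 ± 0.00310 against 2.34 ± 0.987 CPM (-6.13 ± 0.70), stdh-2 (-3.78 ± 0.63), drd-10 (-2.92 ± 0.39), cyp-14A4 (-2.11 ± 0.30) and bcmo-2, of the beta-carotene oxygenase family (-1.38 ± 0.17).

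Cadmium-responsive genes were lower in ns889 without mold: of 7 metal response genes 2 were lower, cdr-2 (-1.48 ± 0.23) and cdr-4 (-1.17 ± 0.13), and 0 higher (0 higher and 3 lower adjusted over the list alone). Camera on metal response genes gave adjusted p = 1.85e-05 (adjusted p = 0.226 with an estimated correlation). Cytochrome P450 genes split, with 3 higher, cyp-13A2 (1.73 ± 0.30) and cyp-13A5 (1.19 ± 0.20) among them, and 3 lower (3 higher and 5 lower adjusted over the list alone). Of 64 UDP-glycosyltransferase genes 3 were higher and 5 lower (6 higher and 6 lower adjusted over the list alone), among the latter ugt-62 (-1.13 ± 0.17). Ribosomal protein genes were slightly higher as a list (median 0.15), with 3 of 78 past the threshold (4 higher adjusted over the list alone), rpl-24.2 (0.69 ± 0.065) among them. Camera on ribosomal protein genes gave adjusted p = 9.87e-08 (adjusted p = 0.996 with an estimated correlation). Of 10 splits of the 6 libraries without mold, the real one included, 7 called as many lists as the real split (8) or more. Chance thus stays open for the lists of this comparison. Of 19 genes of the endoplasmic reticulum unfolded protein response only the chaperone gene dnj-27 rose (0.69 ± 0.12, 2 higher adjusted over the list alone), and hsp-4 did not pass (-0.088 ± 0.057, adjusted p = 0.660). Camera on endoplasmic reticulum unfolded protein response genes gave adjusted p = 0.0373 (adjusted p = 0.491 with an estimated correlation). nhr-45 (WBGene00003635, chromosome X, 4656433 to 4660318) was higher in ns889 at 25.6 ± 0.541 against 15.3 ± 2.11 CPM (0.74 ± 0.11, adjusted p = 0.00145). hsp-6, a mitochondrial chaperone gene, was also higher (0.31 ± 0.068, adjusted p = 0.0248). UDP-glycosyltransferase genes numbered 2 higher and 3 lower without WT without mold replicate 2 or 3 or ns889 without mold replicate 1 or 2. Ribosomal protein genes numbered 1 higher and 0 lower without any 1 of the 6 libraries. Endoplasmic reticulum unfolded protein response genes numbered 3 higher and 0 lower without WT without mold replicate 1. The endoplasmic reticulum unfolded protein response list no longer passed camera without WT without mold replicate 2 (adjusted p = 0.128), WT without mold replicate 3 (adjusted p = 0.0947) and ns889 without mold replicate 1 (adjusted p = 0.0904, range with 1 library left out 0.0136 to 0.128).

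By edgeR's test with Benjamini-Hochberg adjustment 411 genes were higher and 77 lower in ns889 without mold, all 488 without overlap between the replicates, as were 3109 of the tested genes against 10% by chance. The lower count was 211 without WT without mold replicate 1, 48 without its replicate 3 and 43 without ns889 without mold replicate 2. Leaving out WT without mold replicate 1 and WT with mold replicate 3, chosen after seeing the data, gave 751 and 566. hsp-6 was lost without ns889 without mold replicates 1 (adjusted p = 0.0670), 2 (0.135) and 3 (0.0762, range over its alternatives 0.00436 to 0.135). cyp-13A12 and stdh-2 were lost with limma-voom (adjusted p = 0.0711, range 2.74e-19 to 0.0711, and 0.0614, range 7.6e-07 to 0.0614).

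**Figure D3:**
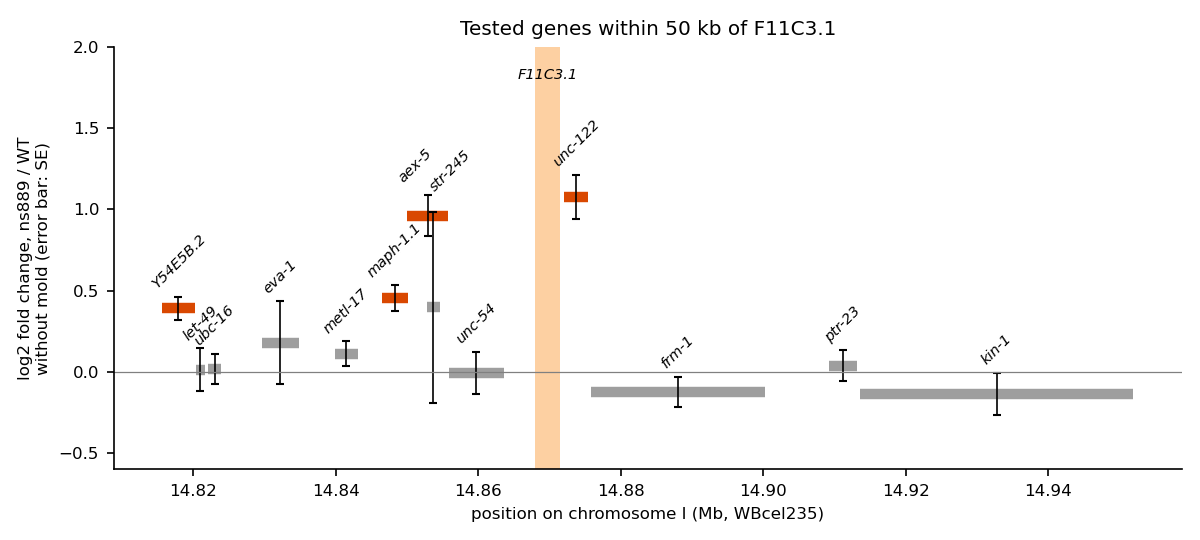
Log2 fold change of ns889 against WT without mold (± SE) of the 13 tested genes within 50 kb of F11C3.1 on chromosome I, with a shaded band over F11C3.1 and orange bars for genes past the threshold. Y54E5B.2 (0.39), maph-1.1 (0.45), aex-5 (0.96) and unc-122 (1.08), chosen after their values were seen, were higher in ns889. Y54E5B.2 was lost without ns889 without mold replicate 2 (adjusted p = 0.0619), with the first run only (0.0503) and in a fit of only the 2 groups compared (0.0627, range over its alternatives 0.000807 to 0.0627).

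The fourth comparison set ns889 against WT when both met the mold. Several detoxification genes that rose in WT were lower in ns889. cyp-14A4 was at 0.456 ± 0.117 CPM in ns889 and 29.1 ± 6.83 CPM in WT (mean ± SD, n = 3), a log2 fold change of -5.99 ± 0.28 (SE, adjusted p = 3.2e-07). cyp-33C2 (-6.47 ± 0.65), gst-44 (-5.15 ± 0.36), stdh-2 (-5.25 ± 0.44), gst-33 (-4.27 ± 0.42) and bcmo-2 (-3.40 ± 0.17) were lower too. cyp-13A8, chosen after its values were seen, was at 27.8 against 96.9 CPM (-1.80 ± 0.34, adjusted p = 0.00790). It was lost in a fit of only the 2 groups compared (adjusted p = 0.0991) and with WT without mold replicate 1 and WT with mold replicate 3 both left out (0.0545, range over its alternatives 1.26e-05 to 0.0991). Further genes lower in ns889 were drd-10 (-5.16 ± 0.44), T16G1.6 (-3.17 ± 0.33), thn-2 (-3.20 ± 0.23) and ugt-1 (-2.92 ± 0.32). F11C3.1 was again higher (8.09 ± 0.21, 292 ± 36.3 against 1.08 ± 0.293 CPM). So were H17B01.2 (3.94 ± 0.19), C08F11.7 (3.21 ± 0.21), gst-38 (3.44 ± 0.49), dod-24 (2.85 ± 0.21) and F55G11.2 (2.70 ± 0.23).

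Of 10 splits of the 6 libraries with mold, the real one included, 8 called as many lists as the real split (13) or more. Chance thus stays open for the lists of this comparison. With mold, 15 of 69 cytochrome P450 genes were lower in ns889 and 2 higher (4 higher and 19 lower adjusted over the list alone). Camera on cytochrome P450 genes gave adjusted p = 4.69e-06 (adjusted p = 0.238 with an estimated correlation). Of 13 lysozyme genes 4 were lower and 0 higher (0 higher and 4 lower adjusted over the list alone), with ilys-2 (-6.82 ± 0.41) and ilys-5 (-1.72 ± 0.17) among them. Camera on lysozyme genes gave adjusted p = 2.06e-08 (adjusted p = 0.130 with an estimated correlation). Glutathione S-transferase genes were higher in 3 and lower in 5 of 48 cases (5 higher and 9 lower adjusted over the list alone). UDP-glycosyltransferase genes were higher in 5 and lower in 8 of 64 (10 higher and 9 lower adjusted over the list alone). ugt-41 (-2.46 ± 0.13) and ugt-62 (-1.98 ± 0.18) were among the latter. The metal response list held 3 lower genes of 7, cdr-4 (-1.77 ± 0.13) among them, and 0 higher (0 higher and 4 lower adjusted over the list alone). Camera on metal response genes gave adjusted p = 3.81e-06 (adjusted p = 0.130 with an estimated correlation). Yolk protein genes were lower in 5 of 6 cases (0 higher and 6 lower adjusted over the list alone), vit-2 (-0.72 ± 0.092) and vit-6 (-0.54 ± 0.094) among them. Camera on vitellogenin genes gave adjusted p = 2.06e-08 (adjusted p = 0.343 with an estimated correlation). nhr-45 was higher (1.13 ± 0.11, adjusted p = 6.21e-05), as were gst-4 (1.45 ± 0.20, adjusted p = 0.000993) and irg-5 (2.35 ± 0.28). UDP-glycosyltransferase genes numbered 3 higher and 8 lower without WT with mold replicate 2 or 3 or ns889 with mold replicate 2 or 3, and 2 and 8 without ns889 with mold replicate 1. Vitellogenin genes numbered 0 higher and 3 lower without WT with mold replicate 2 or 3 or ns889 with mold replicate 2 or 3.

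More cuticle genes were higher than lower in ns889 against WT with mold: 20 of 130 collagen genes were higher and 3 lower (51 higher and 14 lower adjusted over the list alone). Camera on collagen genes gave adjusted p = 1.14e-06 (adjusted p = 0.774 with an estimated correlation). Of 30 moulting and cuticle genes 7 were higher and 0 lower (21 higher and 0 lower adjusted over the list alone), bli-6 among them (1.17 ± 0.14). Camera on moulting and cuticle genes gave adjusted p = 5.52e-08 (adjusted p = 0.568 with an estimated correlation). Of 33 proteasome genes 5 were slightly lower and 0 higher (0 higher and 22 lower adjusted over the list alone). Camera on proteasome genes gave adjusted p = 2.06e-08 (adjusted p = 0.568 with an estimated correlation). Of 52 sperm genes 7 were higher and 0 lower (10 higher and 0 lower adjusted over the list alone), spe-42 (1.39 ± 0.23) among them. Camera on sperm genes gave adjusted p = 8.08e-05 (adjusted p = 0.781 with an estimated correlation). Of 21 oocyte and eggshell genes 3 were lower and 0 higher (0 higher and 3 lower adjusted over the list alone). Camera on oocyte and eggshell genes gave adjusted p = 5.25e-05 (adjusted p = 0.781 with an estimated correlation). A difference in developmental timing was not tested for these lists or the yolk protein genes in this comparison, and stays open. The mean log2 deviation of the collagen list was 0.12, -0.46 and -1.01 in replicates 1 to 3 of WT with mold and 0.62, 0.60 and 0.57 in ns889 with mold. Collagen genes numbered 56 higher and 10 lower without WT with mold replicate 1, 1 and 0 without WT with mold replicate 2, 3 and 1 without WT with mold replicate 3, 5 and 1 without ns889 with mold replicate 1, 4 and 0 without ns889 with mold replicate 2, and 10 and 3 without ns889 with mold replicate 3. Moulting and cuticle genes numbered 17 higher and 0 lower without WT with mold replicate 1, 3 and 0 without WT with mold replicate 2, 1 and 0 without WT with mold replicate 3 or ns889 with mold replicate 1, and 4 and 0 without ns889 with mold replicate 2 or 3. Proteasome genes numbered 0 higher and 11 lower without WT with mold replicate 1, 0 and 0 without WT with mold replicate 2 or ns889 with mold replicate 1, 2 or 3, and 0 and 1 without WT with mold replicate 3. Sperm genes numbered 11 higher and 0 lower without WT with mold replicate 1, 3 and 0 without WT with mold replicate 2 or ns889 with mold replicate 2, 2 and 0 without WT with mold replicate 3 or ns889 with mold replicate 3, and 4 and 0 without ns889 with mold replicate 1. Oocyte and eggshell genes numbered 0 higher and 1 lower without WT with mold replicate 2 or 3 or ns889 with mold replicate 3, and 0 and 0 without ns889 with mold replicate 2.

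**Figure D4:**
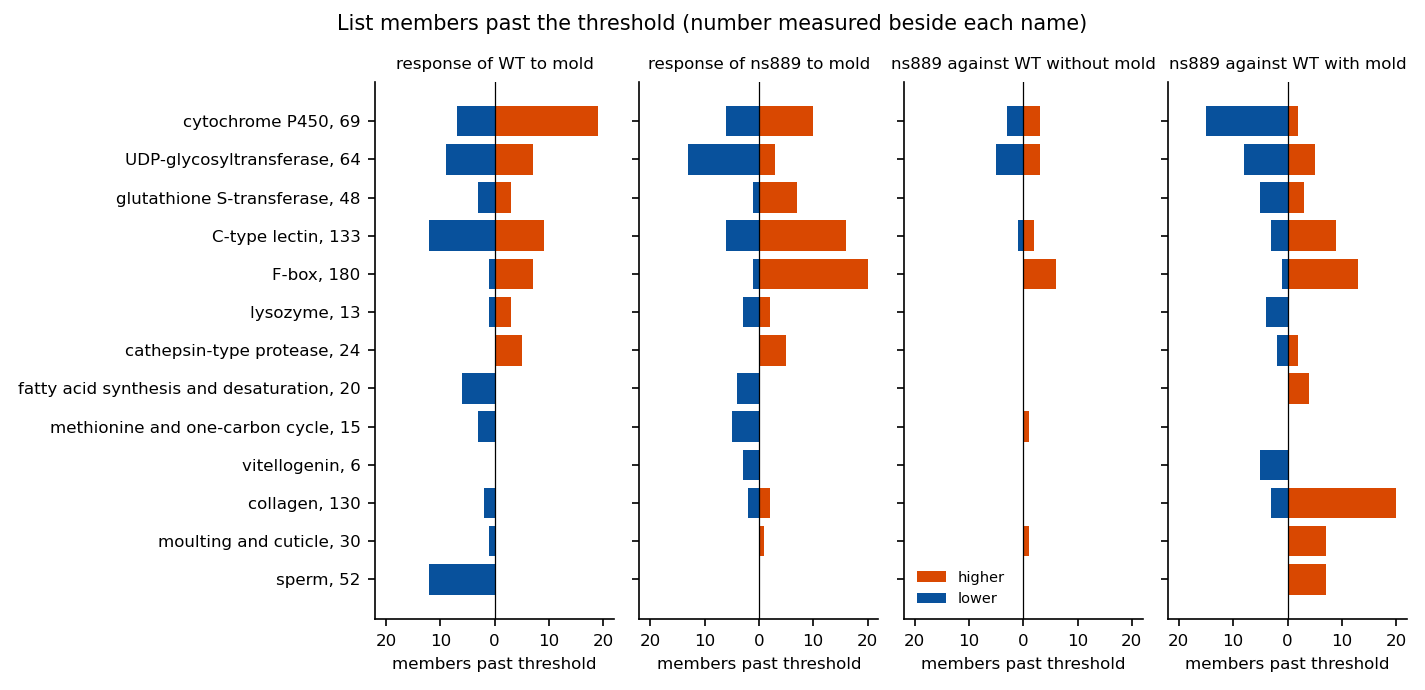
Number of members past the threshold (bars to the right, higher; bars to the left, lower) in 13 gene lists for the 4 comparisons of groups, with the number of measured members beside each name. Of 69 cytochrome P450 genes 15 were lower and 2 higher in ns889 than in WT with mold (14 to 15 and 2 to 3 with 1 library left out). Camera on cytochrome P450 genes gave adjusted p = 4.69e-06 (adjusted p = 0.238 with an estimated correlation).

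**Figure D5:**
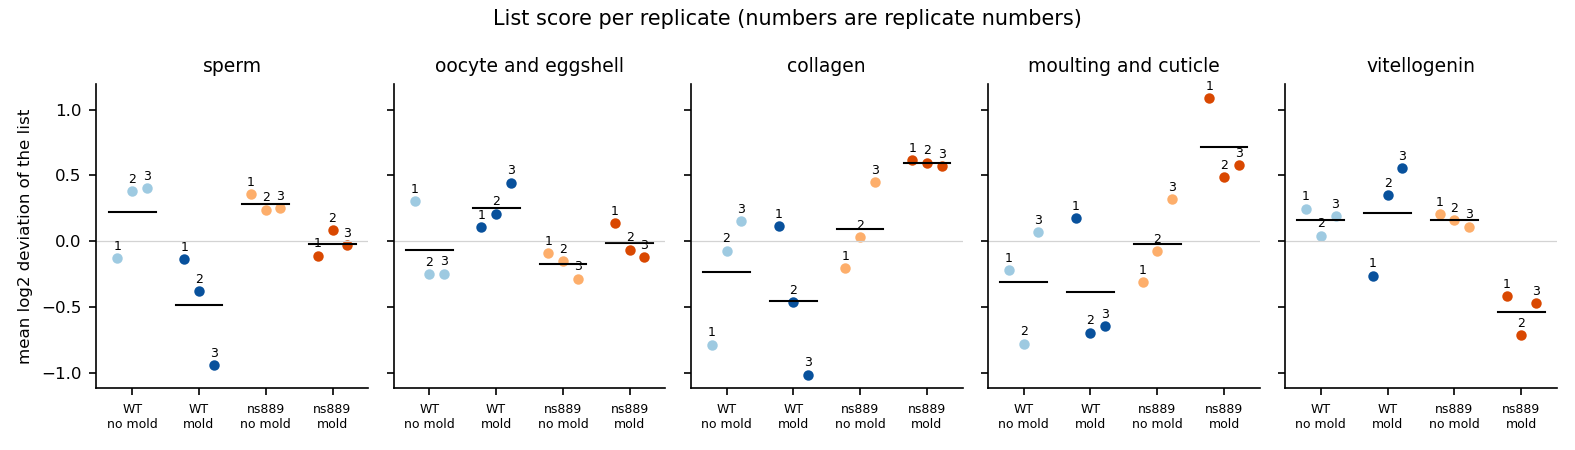
Mean log2 deviation of 5 gene lists in each replicate, numbered by replicate, with a black line at the group mean of 3. Replicates of WT with mold spread from -0.94 to -0.14 for the sperm list and from -1.01 to 0.12 for the collagen list, and those of ns889 with mold from 0.57 to 0.62 for collagen.

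edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment placed 870 genes higher and 273 lower in ns889 with mold, 1138 of 1143 without overlap between the replicates, as were 5330 of the tested genes against 10% by chance. Without WT with mold replicate 1 the counts were 1326 and 542. They were 408 and 137 without its replicate 2, 506 higher without its replicate 3, and 520 and 155, 477 and 117, and 496 and 175 without ns889 with mold replicates 1, 2 and 3. Without WT without mold replicate 1 and WT with mold replicate 3, chosen after seeing the data, 1302 and 571 were placed. hsp-6 passed narrowly (0.25 ± 0.068, adjusted p = 0.0485) and was lost without WT with mold replicate 2 (adjusted p = 0.135) or 3 (0.114) and without ns889 with mold replicates 1 (0.117), 2 (0.0561) and 3 (0.147, range over its alternatives 0.0115 to 0.147).

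The last comparison asked whether the response to mold itself differed between the genotypes, by the change in ns889 minus the change in WT. The responses differed in 22 genes, 6 with a higher and 16 with a lower change in ns889. dod-24 went from 25.1 to 212 CPM with mold in ns889 and from 31.3 to 29.4 CPM in WT (log2 difference 3.17 ± 0.28, SE, n = 3 per group, adjusted p = 0.00120). irg-5 (2.96 ± 0.38), F55G11.2 (2.45 ± 0.32), the C-type lectin gene clec-3 (2.65 ± 0.32), C32H11.4 (2.94 ± 0.47) and F10D2.10 (1.20 ± 0.20) also had the higher change in ns889. dod-24, C32H11.4 and F55G11.2 lie near each other on chromosome IV (from 12921264 to 12969289). The lysozyme gene ilys-2 went from 0.249 to 5.66 CPM in WT but from 0.109 to 0.0491 CPM in ns889 (-5.62 ± 0.59, adjusted p = 0.00200). The thaumatin-like gene thn-1 went from 0.709 to 15.9 CPM in WT but from 0.198 to 0.128 CPM in ns889 (-5.11 ± 0.50, adjusted p = 0.00167).

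The other genes with a lower change in ns889 came from several families. They were the detoxification genes cyp-33C2 (-5.60 ± 0.90), gst-44 (-4.27 ± 0.50), cyp-14A4 (-3.88 ± 0.42), ugt-37 (-3.41 ± 0.42) and ugt-41 (-1.63 ± 0.18). Also in this group were the lysozyme genes lys-7 (-2.07 ± 0.34) and ilys-5 (-1.58 ± 0.24), thn-2 (-3.10 ± 0.31), the cathepsin B-like gene cpr-1 (-2.15 ± 0.30), the lipase gene lipl-3 (-3.18 ± 0.52), bcmo-2 (-2.02 ± 0.23), ZK697.14 (-3.86 ± 0.45), F59B1.8 (-1.17 ± 0.16) and vem-1 (-0.94 ± 0.12). Of 13 lysozyme genes 3 had a lower change in ns889 and 0 a higher one (0 higher and 4 lower adjusted over the list alone). Camera on lysozyme genes gave adjusted p = 1.58e-11 (adjusted p = 0.0548 with an estimated correlation). Of 69 cytochrome P450 genes 2 had a lower and 0 a higher one (0 higher and 4 lower adjusted over the list alone). Camera on cytochrome P450 genes gave adjusted p = 6.16e-05 (adjusted p = 0.216 with an estimated correlation). Of 8 infection response genes 1 had a higher change (5 higher and 0 lower adjusted over the list alone). Camera on infection response genes gave adjusted p = 2.21e-10 (adjusted p = 0.135 with an estimated correlation). Of 9 dod genes 1 had a higher change (3 higher and 0 lower adjusted over the list alone). Camera on dod genes gave adjusted p = 2.05e-08 (adjusted p = 0.0116 with an estimated correlation). gst-4 did not pass (1.45 ± 0.28, adjusted p = 0.122), nor did nhr-45 (0.38 ± 0.15, adjusted p = 0.870). gst-4 passed with DESeq2 (adjusted p = 0.00011), without WT without mold replicate 1 (0.0106), without replicate 1 in every group (0.00471) and without WT without mold replicate 1 and WT with mold replicate 3 (0.0415, range over its alternatives 0.00011 to 0.398). Lysozyme genes numbered 0 higher and 1 lower without WT without mold replicate 3, WT with mold replicate 2, ns889 without mold replicate 1, 2 or 3 or ns889 with mold replicate 2. Cytochrome P450 genes numbered 0 higher and 1 lower without WT without mold replicate 1, 2 or 3, ns889 without mold replicate 1, 2 or 3 or ns889 with mold replicate 2 or 3. dod genes numbered 2 higher and 0 lower without WT without mold replicate 1, WT with mold replicate 1 or ns889 without mold replicate 1.

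These calls came from the interaction contrast in edgeR with Benjamini-Hochberg adjustment. In it 754 of 16980 tested genes had an unadjusted p under 0.05, fewer than chance alone would give. The other contrasts had 2000 to 4252 such genes. With WT without mold replicate 1 and WT with mold replicate 3 left out, chosen after seeing the data, 85 genes had a higher and 29 a lower change. The higher count was 24 without WT without mold replicate 1. Leaving out 1 library lost 2 to 7 of the 22 genes (adjusted p 0.0505 to 0.202), each time from among C32H11.4, F10D2.10, cyp-33C2, lys-7, ilys-5, lipl-3 and vem-1. Over 21 alternatives, left-out libraries included, cyp-33C2 was lost in 15, C32H11.4 in 13, F10D2.10 and ilys-5 in 12 each and lys-7 in 10. lipl-3 was lost in 11 of 20. vem-1 was lost without ns889 with mold replicate 2 (adjusted p = 0.0592, range over its alternatives 2.03e-06 to 0.0592), and gst-44 and cyp-14A4 with limma-voom (adjusted p = 0.190, range 4.56e-18 to 0.190, and 0.0540, range 7.47e-20 to 0.0540). cpr-1 was lost with no filter (adjusted p = 0.0815, range 1.15e-09 to 0.0815), and cyp-33C2 with limma-voom (adjusted p = 0.898, range 1.46e-07 to 0.898).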

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

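The tests of timing, of the libraries that stood apart and of exchanged labels for the sperm genes, the scaling test and the splits of the difference of the responses were chosen only after the results were seen. The responses to mold differed between the genotypes by the interaction contrast in 22 genes. The log2 differences, ns889 minus WT, were dod-24 (3.17), irg-5 (2.96), C32H11.4 (2.94), clec-3 (2.65), F55G11.2 (2.45), F10D2.10 (1.20) for the higher ones. For the lower ones they were vem-1 (-0.94), F59B1.8 (-1.17), ilys-5 (-1.58), ugt-41 (-1.63), bcmo-2 (-2.02), lys-7 (-2.07), cpr-1 (-2.15), thn-2 (-3.10), lipl-3 (-3.18), ugt-37 (-3.41), ZK697.14 (-3.86), cyp-14A4 (-3.88), gst-44 (-4.27), thn-1 (-5.11), cyp-33C2 (-5.60), ilys-2 (-5.62).

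By camera on the same contrast the responses also differed in 18 lists. Median log2 differences were above 0 for these lists: infection response gene (1.15), moulting and cuticle (0.81), downstream of DAF-16 (0.70), collagen (0.51), sperm (0.35), major sperm protein (0.32), pals family, intracellular pathogen response (0.30), oxidative stress defence (0.026). They were below 0 for these: respiratory chain, nuclear-encoded (-0.084), UDP-glycosyltransferase (-0.084), proteasome (-0.086), oocyte and eggshell (-0.12), lysozyme (-0.12), propionate breakdown (-0.14), cytochrome P450 (-0.15), hypoxia and hydrogen sulfide response (-0.30), cytosolic heat shock (-0.44), vitellogenin (-0.83). Only the dod list passed with an estimated correlation (adjusted p = 0.0116 with an estimated correlation). The UDP-glycosyltransferase list no longer passed camera without WT without mold replicate 1 (adjusted p = 0.390), WT with mold replicate 1 (adjusted p = 0.0532) and ns889 without mold replicate 3 (adjusted p = 0.0577, range with 1 library left out 0.000438 to 0.390). The pals family, intracellular pathogen response list no longer passed camera without WT without mold replicate 2 (adjusted p = 0.219), WT with mold replicate 1 (adjusted p = 0.230), WT with mold replicate 2 (adjusted p = 0.102), ns889 without mold replicate 1 (adjusted p = 0.181), ns889 without mold replicate 2 (adjusted p = 0.0958), ns889 with mold replicate 1 (adjusted p = 0.0551), ns889 with mold replicate 2 (adjusted p = 0.0826) and ns889 with mold replicate 3 (adjusted p = 0.138, range with 1 library left out 0.0203 to 0.230). The oxidative stress defence list no longer passed camera without WT without mold replicate 1 (adjusted p = 0.129), WT with mold replicate 1 (adjusted p = 0.0779), WT with mold replicate 2 (adjusted p = 0.0789), ns889 without mold replicate 3 (adjusted p = 0.0664) and ns889 with mold replicate 1 (adjusted p = 0.0934, range with 1 library left out 0.00723 to 0.129). The propionate breakdown list no longer passed camera without WT with mold replicate 1 (adjusted p = 0.0688) and ns889 with mold replicate 2 (adjusted p = 0.0729, range with 1 library left out 0.000506 to 0.0729). The respiratory chain, nuclear-encoded list no longer passed camera without WT without mold replicate 1 (adjusted p = 0.0898), WT with mold replicate 1 (adjusted p = 0.272) and ns889 with mold replicate 2 (adjusted p = 0.124, range with 1 library left out 1.32e-06 to 0.272). The proteasome list no longer passed camera without WT without mold replicate 3 (adjusted p = 0.0545) and ns889 with mold replicate 2 (adjusted p = 0.177, range with 1 library left out 0.00032 to 0.177). The major sperm protein list no longer passed camera without WT with mold replicate 3 (adjusted p = 0.300, range with 1 library left out 1.27e-09 to 0.300). The oocyte and eggshell list no longer passed camera without WT without mold replicate 2 (adjusted p = 0.292), WT without mold replicate 3 (adjusted p = 0.306), WT with mold replicate 3 (adjusted p = 0.354), ns889 without mold replicate 1 (adjusted p = 0.0630), ns889 with mold replicate 2 (adjusted p = 0.0505) and ns889 with mold replicate 3 (adjusted p = 0.114, range with 1 library left out 2.46e-08 to 0.354).

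The 22 genes could reflect a difference in developmental timing between the libraries. With the oocyte and collagen scores as covariates a median of 98.4% of the difference remained (95.8 to 113% with 1 library left out), and 17 of 22 stayed past the threshold, which argues against timing as the whole cause. Scaling is argued against as well, since 1 common shift of all genes cannot yield the 6 higher and 16 lower differences: 15 of 22 stayed more than 2 SE from the shift that explains the most. Splits that exchanged the genotypes of the same number of libraries in both conditions gave as many genes in 1 of 82 (real 22, highest other 0 by edgeR). The others mix both genotypes within groups, which adds the genotype effect to the spread, so few calls were likely in advance. Chance can therefore not be excluded by this test, which was chosen after a first draw. That draw gave as many in 5 of 100 (highest other 1766, with the genotypes of all libraries with mold exchanged). The 4 others among these 5 all exchanged unequal numbers in the conditions, which carries the genotype effect into the contrast, so the draw is no test of chance. A difference in the response of the genotypes stays open too.

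The lower sperm genes with mold in WT may come from a difference in developmental timing. With the oocyte and eggshell score as a covariate 53.9% of the median log2 fold change remained (-0.62 became -0.34; 22.4 to 62.9% with 1 library left out), so timing and mold cannot be told apart for these genes. Without WT without mold replicate 1 129% remained, without WT with mold replicate 3 69.4% and without both 99.6%, which argues against these libraries as the whole cause of the shift. The number of genes called did hang on them: 32, 1 and 30 of 52 genes were lower in these fits, against 12 with all libraries. Exchanged labels of the replicates 1 are argued against by lact-6, at 17.4 CPM in WT without mold replicate 1 and at most 0.0635 CPM in any library with mold. The sperm list was lower with mold in ns889 as well (median log2 fold change -0.29, 0 of 52 genes past the threshold by edgeR), where timing was not tested. An effect of the mold on sperm genes was not tested apart from timing and stays open.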

How the results depend on the processing

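The test of both WT libraries left out together was chosen only after the results were seen. Log2 fold changes of the named genes kept their sign under every alternative run except hsp-6, nhr-45 and nhr-156 in the response of WT, none of which passed where reversed. hsp-6 was at -0.044 with replicate 1 left out in every group and -0.0054 with both libraries left out, and at -0.017 to 0.10 with 1 library left out, below 0 without WT without mold replicate 1. nhr-45 was at -0.0030 with the filter of 5 CPM, -0.063 with replicate 1 left out in every group and -0.015 with both libraries left out, and at -0.053 to 0.15 with 1 library left out, below 0 without WT without mold replicate 1 or WT with mold replicate 2. nhr-156 was at -0.0090 with no filter, -0.032 with the filter of 5 CPM, -0.0056 with only the 2 groups compared in the fit, -0.18 with replicate 1 left out in every group and -0.12 with both libraries left out, and at -0.11 to 0.14 with 1 library left out, below 0 without WT without mold replicate 1 or WT with mold replicate 1 or 3. RLE size factors, no filter and the first run only moved no count of genes by over 1.5 times. RLE size factors moved no count of lists by over 1.5 times either. Lists were tested again only with RLE size factors, the filter of 5 CPM, the replicate block, an estimated correlation and replicates left out. With DESeq2 the counts were 500 higher and 1756 lower for the WT response, 594 higher and 385 lower for the ns889 response, 197 lower for ns889 without mold, 1471 higher and 439 lower for ns889 with mold, 46 higher and 32 lower for the difference. Counts with the filter of 5 CPM were 92 higher and 114 lower for the WT response, 132 higher and 134 lower for the ns889 response, 43 lower for ns889 without mold, 524 higher and 145 lower for ns889 with mold, 3 higher and 8 lower for the difference, 46 higher and 49 lower for shared genes, 4 higher for the WT response lists, 6 lower for the difference lists. With limma-voom the counts were 172 higher and 174 lower for the WT response. Counts with the replicate block were 162 higher and 150 lower for the WT response, 81 higher for shared genes. With only the 2 groups compared in the fit the counts were 47 higher and 36 lower for the WT response, 779 higher and 855 lower for the ns889 response, 266 higher for ns889 without mold. Counts with a minimum absolute log2 fold change of 1 were 149 higher and 403 lower for the WT response, 210 higher and 85 lower for the ns889 response, 118 higher and 42 lower for ns889 without mold, 472 higher and 90 lower for ns889 with mold, 73 higher and 53 lower for shared genes. With replicate 1 left out in every group the counts were 2883 higher and 3304 lower for the WT response, 222 lower for ns889 without mold, 2673 higher and 1440 lower for ns889 with mold, 587 higher and 116 lower for the difference, 6 higher and 11 lower for the WT response lists, 5 higher for ns889 without mold lists. Counts with WT without mold replicate 1 and WT with mold replicate 3 both left out were 1642 higher and 2218 lower for the WT response, 809 higher and 1215 lower for the ns889 response, 751 higher and 566 lower for ns889 without mold, 571 lower for ns889 with mold, 85 higher and 29 lower for the difference, 323 higher and 884 lower for shared genes, 13 lower for ns889 with mold lists. With an estimated correlation the counts were 0 higher and 0 lower for the WT response lists, 1 higher and 0 lower for the ns889 response lists, 0 higher and 0 lower for ns889 without mold lists, 0 higher and 0 lower for ns889 with mold lists, 1 higher and 0 lower for the difference lists. With 1 library left out, counts ran from 97 to 2263 higher and 62 to 2547 lower for WT response, 276 to 458 higher and 43 to 211 lower for ns889 without mold, 4 to 24 higher and 11 to 21 lower for difference, 52 to 197 higher and 46 to 220 lower for shared genes, 3 to 11 higher and 4 to 9 lower for WT response lists, 1 to 4 higher and 4 to 6 lower for ns889 without mold lists, 7 to 10 higher and 6 to 14 lower for difference lists, 408 to 1326 higher and 117 to 542 lower for ns889 with mold, 4 to 8 higher and 7 to 12 lower for ns889 with mold lists, 128 to 256 higher and 80 to 162 lower for ns889 response, 9 to 16 higher and 8 to 14 lower for ns889 response lists. The smaller counts with a fold minimum follow from its construction; for the others the cause was not tested. Of 18 same-numbered pairs of libraries 6 correlated above 0.1 (-0.323 to 0.297), which shows no clear pairing by replicate number. A batch by replicate number is not excluded by this. Replicate 1 of every group had 1 run where replicates 2 and 3 had 2, and leaving it out moved the counts as given above. At these depths 3 counts set the floor, and small changes are limited by the spread of 3 replicates.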

Other observations

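The test of genes near F11C3.1 and the splits of the difference of the responses were chosen only after the results were seen. Of 73 pharynx markers the counts were 0 higher and 2 lower in the WT response, 0 higher and 1 lower in the ns889 response, 2 higher and 0 lower in ns889 without mold, 7 higher and 0 lower in ns889 with mold. Of 12 intestine markers they were 1 higher and 0 lower in the WT response, 0 higher and 0 lower in the ns889 response, 1 higher and 0 lower in ns889 without mold, 0 higher and 0 lower in ns889 with mold. Of 16 body wall muscle markers they were 0 higher and 0 lower in the WT response, 0 higher and 0 lower in the ns889 response, 1 higher and 0 lower in ns889 without mold, 0 higher and 0 lower in ns889 with mold. Pharynx markers in the WT response numbered 5 higher and 8 lower without WT without mold replicate 1, 0 and 0 without WT without mold replicate 2 or 3 or WT with mold replicate 3, 1 and 6 without WT with mold replicate 1, and 0 and 1 without WT with mold replicate 2. The pharynx marker list in the WT response passed camera without WT with mold replicate 1 (adjusted p = 0.0485, range with 1 library left out 0.0485 to 0.396). Pharynx markers in the ns889 response numbered 0 higher and 0 lower without ns889 without mold replicate 1, 2 or 3 or ns889 with mold replicate 1 or 2, and 0 and 2 without ns889 with mold replicate 3. Pharynx markers in ns889 without mold numbered 1 higher and 1 lower without WT without mold replicate 1, and 1 and 0 without WT without mold replicate 2 or 3 or ns889 without mold replicate 1, 2 or 3. Pharynx markers in ns889 with mold numbered 19 higher and 2 lower without WT with mold replicate 1, 1 and 0 without WT with mold replicate 2, 1 and 2 without WT with mold replicate 3, 3 and 0 without ns889 with mold replicate 1, and 2 and 0 without ns889 with mold replicate 2 or 3. The pharynx marker list in ns889 with mold passed camera without WT with mold replicate 1 (adjusted p = 0.0462, range with 1 library left out 0.0462 to 0.351). Body wall muscle markers in the WT response numbered 0 higher and 8 lower without WT without mold replicate 1. The body wall muscle marker list in the WT response no longer passed camera without WT without mold replicate 2 (adjusted p = 0.202), WT without mold replicate 3 (adjusted p = 0.0712) and WT with mold replicate 3 (adjusted p = 0.178, range with 1 library left out 0.00977 to 0.202). The body wall muscle marker list in the ns889 response no longer passed camera without ns889 with mold replicate 1 (adjusted p = 0.0710, range with 1 library left out 0.000203 to 0.0710). Body wall muscle markers in ns889 without mold numbered 1 higher and 1 lower without WT without mold replicate 1, and 0 and 0 without WT without mold replicate 2 or 3 or ns889 without mold replicate 1, 2 or 3. The mean log2 deviation of the pharynx list was 0.043, -0.46 and -0.63 in replicates 1 to 3 of WT with mold and 0.16, 0.34 and 0.35 in ns889 with mold, and camera did not pass there (adjusted p = 0.144). Camera placed the body wall muscle list lower in the WT response (adjusted p = 0.0392, and 0.859 with an estimated correlation) and in the ns889 response (adjusted p = 0.00531, and 0.681 with an estimated correlation).

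Neuron markers (20) gave 0 higher and 0 lower in the WT response, 0 higher and 0 lower in the ns889 response, 0 higher and 0 lower in ns889 without mold, 1 higher and 0 lower in ns889 with mold, and the 10 amphid sheath glia markers gave 0 in every comparison by edgeR. FMRFamide-like neuropeptide genes (30) gave 0 higher and 0 lower in the WT response, 0 higher and 1 lower in the ns889 response, 0 higher and 0 lower in ns889 without mold, 0 higher and 0 lower in ns889 with mold. Camera placed this list lower in the ns889 response (adjusted p = 0.0161, and 0.735 with an estimated correlation). Neuron markers in the WT response numbered 0 higher and 3 lower without WT without mold replicate 1. The neuron marker list in the ns889 response passed camera without ns889 with mold replicate 3 (adjusted p = 0.0220, range with 1 library left out 0.0220 to 0.559). Neuron markers in ns889 with mold numbered 2 higher and 0 lower without WT with mold replicate 1, and 0 and 0 without WT with mold replicate 2 or 3 or ns889 with mold replicate 2 or 3. FMRFamide-like neuropeptide genes in the WT response numbered 0 higher and 1 lower without WT without mold replicate 1 or WT with mold replicate 1. FMRFamide-like neuropeptide genes in the ns889 response numbered 0 higher and 2 lower without ns889 with mold replicate 3. The FMRFamide-like neuropeptide list in the ns889 response no longer passed camera without ns889 with mold replicate 1 (adjusted p = 0.107, range with 1 library left out 0.00324 to 0.107). FMRFamide-like neuropeptide genes in ns889 with mold numbered 0 higher and 1 lower without ns889 with mold replicate 3. Intestine markers in the WT response numbered 1 higher and 2 lower without WT without mold replicate 1. Intestine markers in ns889 without mold numbered 1 higher and 1 lower without WT without mold replicate 1. Intestine markers in ns889 with mold numbered 0 higher and 2 lower without WT with mold replicate 1.

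F11C3.1 was far higher in ns889 in both conditions. It may lie near a change carried by the ns889 strain: 30.8% of tested genes within 50 kb (4 of 13) were higher in ns889 without mold, against 2.42% of all tested genes, and 0.09% of 10000 windows around other genes had as high a share. Reads of the gene unc-122, a neighbour chosen after its values were seen, are argued against as the source, since its CPM reached at most 3.51% of that of F11C3.1. This compares counts per gene only, so reads from sequence beside unc-122 are not covered, and the strand setting is not given. Which change the strain carries was not tested, and an effect of the allele itself stays open.

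Splits of 6 libraries into 3 and 3 number 10, too few for a share under 0.05. For genes, 2 of 10 splits gave as many (real 1064, highest other 3155) in the WT response. The highest split exchanged replicates 2 and 3 of both groups, which is the same as exchanging their replicates 1. The cause of its calls was not tested. For genes in the ns889 response 1 of 10 splits gave as many (real 534, highest other 0), in ns889 without mold 1 of 10 splits gave as many (real 488, highest other 0) and in ns889 with mold 1 of 10 splits gave as many (real 1143, highest other 0). For lists in the WT response 3 of 10 splits gave as many (real 16, highest other 20), in the ns889 response 1 of 10 splits gave as many (real 25, highest other 21), in ns889 without mold 7 of 10 splits gave as many (real 8, highest other 13) and in ns889 with mold 8 of 10 splits gave as many (real 13, highest other 22). With so few splits chance stays open for the genes and the lists of every comparison of groups. In the WT response and in ns889 against WT in both conditions, other splits called as many lists as the real one.

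Of the 82 splits that exchanged the genotypes of the same number of libraries in both conditions, 4 called as many lists in the difference of the responses (real 18, highest other 22, median of the others 11), a share under 0.05. Of 100 splits drawn of 200, 1 shared as many genes between both responses (real 229, highest other 11). Most of the others mix libraries with and without mold within groups, which adds the mold effect to the spread. The test thus argues against no difference with mold at all, and cannot tell how many genes chance would share. A first draw for the difference, of 100 splits of 200, gave as many lists in 5 (highest other 22), but 51 of its splits exchanged unequal numbers in the conditions, which carries the genotype effect into the contrast. The splits with equal numbers were chosen after that. Since the highest of them called more lists than the real split, chance stays open for these lists.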
